A study of Mus musculus with 9 samples.

How the data were processed

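Messenger RNA of cells labelled HT22 was sequenced in 9 libraries, 3 each of control, Hb (oxyhemoglobin) and Hb+NTR1 (oxyhemoglobin and NTR1), after poly(A) selection with a NEBNext Ultra II kit on an Illumina NovaSeq. The sample labels name the line HT22 in the titles and HT-4 as the cell type. The authors' notes name bcl2fastq 2.19.1.403, HISAT2 2.1.0, HTSeq 0.10.0 and the GRCm38 genome. The annotation release, the strand setting and the handling of reads that map to several genes are not given in the sources used here, so genes with near-identical copies or with overlap on the opposite strand are uncertain.

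The deposited count table holds raw counts per gene symbol, not normalised by the authors, for the 9 libraries and 54232 entries. Of these, 98 that repeated both a symbol and all of its counts were removed. Any repeat of a symbol with other counts was kept as a separate entry. The deposited comparison table of the authors holds, for genes of Hb+NTR1 against control, counts equal to those of the count table, a log2 fold change, a p-value and an adjusted p-value. The test behind the authors' log2 values and p-value columns is not given in the sources used here. All genes of that table have an absolute log2 fold change above 2 and an adjusted p under 0.01. Count columns with names beginning in N were taken as the Hb+NTR1 group because the authors' table of that group against control holds only N and C columns. Gene positions and versioned identifiers came from GENCODE M21 on GRCm38, in which 689 identifiers of the authors' table were found, 667 of them with the same start and end.

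Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 13810, and libraries were scaled by TMM factors. All 9 libraries entered 1 quasi-likelihood fit with robust dispersion and a term for group. The common biological coefficient of variation was 6.90%. Each of the 3 comparisons was tested with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Gene lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists with at least 5 measured members, and again with a correlation estimated per list and with fry. Median log2 fold changes of lists are over measured members.

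The 29 lists, the comparisons, the alternatives named next and the rule for naming genes were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls per comparison with at least 5 CPM in the higher group and no overlap of libraries, up to 4 called members of each called list, the 10 largest opposite changes, and a fixed set for the title gene, heme response and apoptosis. Some genes that the rule picked are not reported here. The lists covered heme and iron, antioxidant, cell death, stress, metabolic, proliferation, matrix, signalling and cell type genes. For YAP and SRF targets 2 symbols, Ccn1 and Ccn2, and for erythroid markers 1 symbol, Ahsp, were not in the count table under these current names. Members were matched by symbol only, so the results of the YAP and SRF list leave out Ccn1 and Ccn2, whose levels were not examined.

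The alternatives were DESeq2 size factors in edgeR, no filter on low counts, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, only the 6 libraries of a comparison, a fold change threshold, replicate number as a block, and each library left out in turn. Library totals alone, removal of mitochondrially encoded genes and a split of the libraries shared by 2 comparisons were added after the data had been seen. Overlaps between comparisons were set beside the product of the list sizes over the genes tested and beside 20 simulations without a group effect that shared libraries in the same way. They were also counted with the 3 shared libraries split, 1 in one comparison and 2 in the other, in fits of all 9 libraries.

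The edgeR fit was tested on simulated data for Hb against control, with 50 genes changed at each of 4 sizes. The Hb+NTR1 libraries were drawn there at control levels. The fit called 36% of genes changed 1.25-fold, 78% at 1.5-fold, 84% at 2-fold and 98% at 4-fold. Of its calls, 6.33% were unchanged genes. These shares do not cover the Hb+NTR1 comparisons, in which a majority of tested genes was called. A gene list shifted by 0.5 log2 in the simulation passed camera with the preset correlation and with the estimated one (adjusted p = 4.23e-06), and 0 of 19 lists sharing no gene with it passed. Genes were drawn independently there and no gene outside the list changed. In the real data the same list, the integrated stress response genes, had an estimated correlation of 0.225 in Hb against control. The simulation therefore does not show how either setting performs with correlated genes.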

Results

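Gene expression was measured by RNA sequencing in cells labelled HT22, the name of a mouse hippocampal neuronal line, in 3 groups of 3 libraries. Control cells received no treatment, cells of the Hb group received oxyhemoglobin, the oxygenated blood pigment that red cells release after a bleed, and cells of the Hb+NTR1 group received oxyhemoglobin together with NTR1. The labels of the samples write NTR1 for the added agent and the title of the series writes NGR1. No group received the agent alone. The total count per library ran from 14390296 to 16918242 in control, from 13435891 to 14752309 in Hb and from 13964488 to 14298879 in Hb+NTR1. A gene with 0 counts in a library could have had up to 3 counts, or 0.178 to 0.224 CPM (counts scaled to the library total), and this floor covers counting error only. Levels are given as normalised CPM, mean ± SD over n = 3 libraries, and log2 fold changes as estimate ± SE. P-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 13810 genes tested. The SE was derived as the size of the log2 fold change divided by the square root of the F statistic of that test. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

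The Hb+NTR1 libraries lay apart from the other 6 on the leading principal component, which held 72.7% of the variance, against 6.44% for the next component. Across genes, which are not independent replicates, the correlation of log CPM was 0.986 to 0.989 between control and Hb libraries and 0.944 to 0.951 between Hb and Hb+NTR1 libraries. Within groups it was 0.988 to 0.993. Hb replicate 2 stood further from its group than any other library did, with a chi-square per degree of freedom of 13.2 and 11.04 against the other Hb libraries, where the remaining pairs within a group gave 2.53 to 5.19. Mitochondrially encoded genes took 5.01% ± 0.245 of the counts in control, 4.38% ± 0.220 in Hb and 6.42% ± 0.228 in Hb+NTR1 (SD, n = 3). Of 31 neuronal marker genes fixed beforehand, 24 lay under 1 CPM in control and 7 had no count in any library. Some fibroblast marker genes were abundant in the same libraries, with Col1a2, a chain of type I collagen, at 9098 ± 221 CPM in control. Others were not, with Fap at 0 and Lum at 0.127 CPM in control by library totals. Among the other neuronal markers, Dlg4, Ncam1, Bdnf and Tubb3 had 68.5, 66.6, 34.3 and 31.8 CPM in control by library totals. The identity of the line was not tested and is in doubt from these levels.

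Hb was compared with control to ask what oxyhemoglobin changed in these cells. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, went from 42.4 ± 1.47 to 86.8 ± 7.93 CPM, and Fth1, the ferritin heavy chain that stores iron, went from 1049 ± 61.4 to 1752 ± 223 CPM. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, fell from 239 ± 47.0 to 73.5 ± 3.31 CPM. In all, 504 genes, or 3.65% of those tested, passed an adjusted p of 0.05 by edgeR, 259 higher and 245 lower in Hb, and 51 of them changed at least 2-fold.

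The 10 largest rises by the fixed rule were in Aldh3a1, Prl2c2, Atg9b, Gsta4, Itgb7, Tcim, Shc2, Hmox1, Abca8b and Dmpk, and in each the 3 Hb libraries lay above the 3 control libraries. Aldh3a1, an aldehyde dehydrogenase, rose 3.79-fold from 3.34 ± 0.209 to 12.6 ± 2.45 CPM (log2 fold change 1.92 ± 0.179, edgeR adjusted p = 2.23e-07). Gsta4, a glutathione transferase that detoxifies products of lipid peroxidation, rose 2.49-fold from 106 ± 13.04 to 264 ± 36.4 CPM (log2 fold change 1.32 ± 0.0885, edgeR adjusted p = 4.77e-09). Itgb7, an integrin beta subunit, went from 11.5 ± 1.20 to 26.0 ± 3.87 CPM. Prl2c2 belongs to a family of near-identical genes between which reads can be split, so its rise from 4.96 ± 0.809 to 18.0 ± 2.91 CPM is uncertain. The largest falls were in Thbs1, Ifi202b, Prelp, Igsf10, Acta2, Tgtp2, Egr3, Tas1r1, Fstl1 and Postn, with no overlap between the libraries of both groups. Thbs1 fell 3.25-fold (log2 fold change -1.70 ± 0.108, edgeR adjusted p = 3.73e-08). Acta2, smooth muscle actin, fell from 20.5 ± 5.46 to 9.25 ± 1.01 CPM. Fstl1, a secreted glycoprotein, went from 92.3 ± 5.84 to 43.8 ± 2.53 CPM. Ifi202b and Tgtp2 have near-identical relatives and are likewise uncertain.

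Of the 29 gene lists fixed before the data were examined, 25 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, and 10 passed in Hb against control, 5 up and 5 down. None of these calls, nor any list call in the other comparisons, held with an estimated correlation. NRF2 target genes, the antioxidant program, rose most clearly, with 12 higher, 1 lower and 10 not past the threshold of 23 members, and 15 higher and 1 lower adjusted over the list alone. For NRF2 target genes the median log2 fold change was 0.28, with adjusted p = 3.46e-20. The list had adjusted p = 0.0941 with an estimated correlation. Gsta4, Hmox1, Fth1 and Gclm moved most, and Gclm, a subunit of the enzyme that makes the glutathione precursor, went from 106 ± 11.6 to 165 ± 10.5 CPM. Reads of Fth1 can be shared with its processed pseudogenes. The p53 target genes rose, with 7 higher, 1 lower and 15 not past the threshold of 23 members, and 10 higher and 2 lower adjusted over the list alone. For p53 target genes the median log2 fold change was 0.18, with adjusted p = 1.55e-05, and adjusted p = 0.159 with an estimated correlation. The cell cycle inhibitor Cdkn1a rose from 80.3 ± 5.46 to 108 ± 6.17 CPM. The receptor gene Eda2r rose from 39.6 ± 2.59 to 55.5 ± 1.69 CPM. The pro-apoptotic Bax rose from 29.2 ± 2.82 to 41.7 ± 7.21 CPM. By contrast, the antiproliferative Btg2 fell from 22.4 ± 3.27 to 15.3 ± 0.319 CPM. Without control replicate 2 Bax no longer passed (adjusted p = 0.0833).

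Autophagy and lysosome genes rose, with 6 higher, 0 lower and 20 not past the threshold of 26 members, and 11 higher and 0 lower adjusted over the list alone. For autophagy and lysosome genes the median log2 fold change was 0.16, with adjusted p = 1.63e-05, and adjusted p = 0.165 with an estimated correlation. Gpnmb, a lysosomal membrane glycoprotein, went from 174 ± 5.63 to 222 ± 9.58 CPM. The protease Ctsb went from 204 ± 6.29 to 249.6 ± 6.49 CPM, the autophagy receptor Sqstm1 from 493 ± 22.2 to 601 ± 39.5 CPM and the hexosaminidase subunit Hexa from 72.3 ± 4.37 to 87.7 ± 5.31 CPM. These calls ended without control replicate 2 for Ctsb (adjusted p = 0.0545) and Hexa (adjusted p = 0.171), and without control replicate 1 for Hexa (adjusted p = 0.0703) and Sqstm1 (adjusted p = 0.103). Sqstm1 also missed without control replicate 3 (adjusted p = 0.0620), and Hexa with only the 6 libraries compared (adjusted p = 0.0618). Heat shock genes rose, with 3 higher, 0 lower and 16 not past the threshold of 19 members, and 3 higher and 0 lower adjusted over the list alone. For heat shock genes the median log2 fold change was 0.12, with adjusted p = 1.55e-05, and adjusted p = 0.290 with an estimated correlation. The chaperone genes Hspa4l and Hsph1 went from 241 ± 9.14 to 342 ± 19.2 CPM and from 338 ± 6.04 to 437 ± 9.87 CPM. Hspa1b, whose reads can be shared with Hspa1a, went from 25.9 ± 3.73 to 33.7 ± 2.40 CPM. Hspa1b no longer passed by DESeq2 (adjusted p = 0.0630) or with only the 6 libraries compared (adjusted p = 0.0743). It also missed without control replicate 1, control replicate 3, Hb replicate 1 or Hb replicate 2, at adjusted p = 0.268, 0.104, 0.0899 and 0.0617. Hypoxia and glycolysis genes rose, with 2 higher, 0 lower and 30 not past the threshold of 32 members, and 2 higher and 0 lower adjusted over the list alone. For hypoxia and glycolysis genes the median log2 fold change was 0.082, with adjusted p = 0.00353, and adjusted p = 0.165 with an estimated correlation. The called members were the glycolytic enzymes Hk1, from 191 ± 6.79 to 238 ± 12.9 CPM, and Aldoa, from 405 ± 12.6 to 489 ± 46.4 CPM. Aldoa missed the threshold without control replicate 1, 2 or 3 (adjusted p = 0.0600, 0.114 and 0.154).

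Extracellular matrix genes fell as a group, with 0 higher, 15 lower and 17 not past the threshold of 32 members, and 2 higher and 21 lower adjusted over the list alone. For extracellular matrix genes the median log2 fold change was -0.27, with adjusted p = 1.62e-18, and adjusted p = 0.125 with an estimated correlation. Beside Thbs1, the proteoglycan gene Bgn went from 1159 ± 45.3 to 657 ± 25.8 CPM, the periostin gene Postn from 16.7 ± 2.96 to 8.52 ± 1.80 CPM and the tenascin gene Tnc from 211 ± 21.04 to 142 ± 27.8 CPM. Fibroblast markers, of which several are also in the matrix list, fell, with 0 higher, 4 lower and 5 not past the threshold of 9 members, and 1 higher and 6 lower adjusted over the list alone. For fibroblast markers the median log2 fold change was -0.30, with adjusted p = 9.23e-06, and adjusted p = 0.125 with an estimated correlation. Col1a1, a chain of type I collagen, went from 3624 ± 221 to 2598 ± 262 CPM, and Pdgfra, a growth factor receptor, from 109 ± 10.9 to 78.8 ± 9.73 CPM. Col1a2 went from 9098 ± 221 to 7381 ± 423 CPM. Col1a2 missed without control replicate 3 (adjusted p = 0.0541), as did Tgtp2 (adjusted p = 0.0513), and Tas1r1 missed without control replicate 2 (adjusted p = 0.103). YAP and SRF target genes, which respond to the actin cytoskeleton, fell, with 0 higher, 4 lower and 11 not past the threshold of 15 members, and 0 higher and 4 lower adjusted over the list alone. For YAP and SRF target genes the median log2 fold change was -0.15, with adjusted p = 0.00207, and adjusted p = 0.290 with an estimated correlation. Acta2, Crim1, a transmembrane protein gene, and Amotl2, a junction protein gene, were among the members that fell. Without control replicate 1, 2 or 3 the calls of Crim1 (adjusted p = 0.105, 0.0575 and 0.164) and Amotl2 (adjusted p = 0.253, 0.102 and 0.0513) ended. Amotl2 also missed without Hb replicate 3 (adjusted p = 0.125) and with only the 6 libraries compared (adjusted p = 0.0766). By fry, the heat shock list (adjusted p = 0.0755) and the YAP and SRF list (adjusted p = 0.0924) did not pass. Heme and iron handling (up, fry adjusted p = 0.00569) and astrocyte markers (down, fry adjusted p = 0.0134) passed by fry but not by camera.

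Mitochondrially encoded genes, whose share of the counts was lowest in Hb, fell, with 0 higher, 2 lower and 11 not past the threshold of 13 members, and 0 higher and 4 lower adjusted over the list alone. For mitochondrially encoded genes the median log2 fold change was -0.19, with adjusted p = 1.55e-05, and adjusted p = 0.188 with an estimated correlation. The called members were subunits of respiratory complex I, mt-Nd5, from 3951 ± 193 to 3087 ± 207 CPM, and mt-Nd1, from 9483 ± 862 to 7791 ± 698 CPM. The call of mt-Nd1 ended without control replicate 2 or 3 (adjusted p = 0.272 and 0.194), without Hb replicate 1 or 3 (adjusted p = 0.161 and 0.105) and with only the 6 libraries compared (adjusted p = 0.0844). Cholesterol synthesis genes passed as lower, with 0 higher, 0 lower and 25 not past the threshold of 25 members, and 0 higher and 0 lower adjusted over the list alone. For cholesterol synthesis genes the median log2 fold change was -0.10, with adjusted p = 0.00207, and adjusted p = 0.204 with an estimated correlation.

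The other 15 lists did not pass in Hb against control. Interferon-stimulated genes had 1 higher and 0 lower of 23 (2 and 0 adjusted over the list alone), at a median log2 of 0.16 and adjusted p = 0.0551. Immediate early genes had 2 higher and 5 lower of 25 (4 and 7 adjusted over the list alone), at a median log2 of -0.011 and adjusted p = 0.0722. Oxidative phosphorylation genes had 0 higher and 0 lower of 34 (0 and 0 adjusted over the list alone), at a median log2 of -0.057 and adjusted p = 0.0722. Heme and iron handling had 7 higher and 3 lower of 27 (8 and 3 adjusted over the list alone), at a median log2 of 0.057 and adjusted p = 0.0722. Pro-apoptotic genes had 1 higher and 0 lower of 23 (1 and 0 adjusted over the list alone), at a median log2 of 0.0071 and adjusted p = 0.791. Anti-apoptotic genes had 0 higher and 0 lower of 15 (0 and 0 adjusted over the list alone), at a median log2 of -0.044 and adjusted p = 0.224. Ferroptosis regulators had 2 higher and 1 lower of 20 (2 and 1 adjusted over the list alone), at a median log2 of 0.10 and adjusted p = 0.197. DNA replication genes had 0 higher and 1 lower of 30 (0 and 2 adjusted over the list alone), at a median log2 of -0.040 and adjusted p = 0.214. Mitotic genes had 0 higher and 0 lower of 30 (0 and 0 adjusted over the list alone), at a median log2 of -0.035 and adjusted p = 0.224. Integrated stress response genes had 0 higher and 0 lower of 27 (0 and 0 adjusted over the list alone), at a median log2 of 0.0053 and adjusted p = 0.772. Endoplasmic reticulum chaperones had 0 higher and 0 lower of 22 (0 and 0 adjusted over the list alone), at a median log2 of -0.023 and adjusted p = 0.830. Integrin subunits had 2 higher and 1 lower of 17 (3 and 1 adjusted over the list alone), at a median log2 of 0.077 and adjusted p = 0.326. NF-kB and inflammatory genes had 1 higher and 1 lower of 18 (2 and 1 adjusted over the list alone), at a median log2 of -0.018 and adjusted p = 0.772. Neuronal markers had 0 higher and 1 lower of 8 (0 and 1 adjusted over the list alone), at a median log2 of -0.038 and adjusted p = 0.772. Astrocyte markers had 0 higher and 1 lower of 5 (0 and 1 adjusted over the list alone), at a median log2 of 0.082 and adjusted p = 0.481. The astrocyte list had a mean of -0.073 and a camera direction of down against its positive median, and the chaperone list a mean of 0.016 and a direction of up against its negative median. Some of these lists passed camera at the preset correlation with 1 library left out. Neither the calls of their members nor an estimated correlation were computed in those fits. The oxidative phosphorylation list passed, down, without control replicate 2 (adjusted p = 0.0429) or Hb replicate 2 (1.81e-06), and the heme and iron list, up, without Hb replicate 2 (0.0393). The interferon list passed, up, without control replicate 1, control replicate 3 or Hb replicate 1 (adjusted p = 0.0109, 0.0474 and 0.0240), and the immediate early list, down, without control replicate 1 or Hb replicate 1 (0.0109 and 0.0438). Among the genes fixed for apoptosis and stress, Bcl2 had 7.89 ± 0.650 and 7.67 ± 2.097 CPM, Ddit3 30.7 ± 2.44 and 34.2 ± 4.32 CPM and Slc7a11 34.1 ± 1.42 and 37.0 ± 5.36 CPM in control and Hb, at edgeR adjusted p = 0.944, 0.442 and 0.611.

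The number of genes called in Hb against control depended on single libraries. It was 315, 285 and 286 without control replicate 1, 2 and 3, and 1125 without Hb replicate 2. Under library totals alone, an alternative chosen after the data had been seen, the split became 377 higher and 196 lower, or 65.8% higher against 51.4%. The higher genes were the fewer with no low-count filter (48.4%), by DESeq2 (48.0%), with only the 6 libraries compared (48.8%) and with the replicate number as a block (49.0%). They were also the fewer with any control replicate or Hb replicate 1 or 2 left out (44.6% to 47.4%), so the majority direction was not stable. The 3 libraries of each group did not overlap for 2701 genes, or 19.6%, where chance gives 10%.

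**Figure D1:**
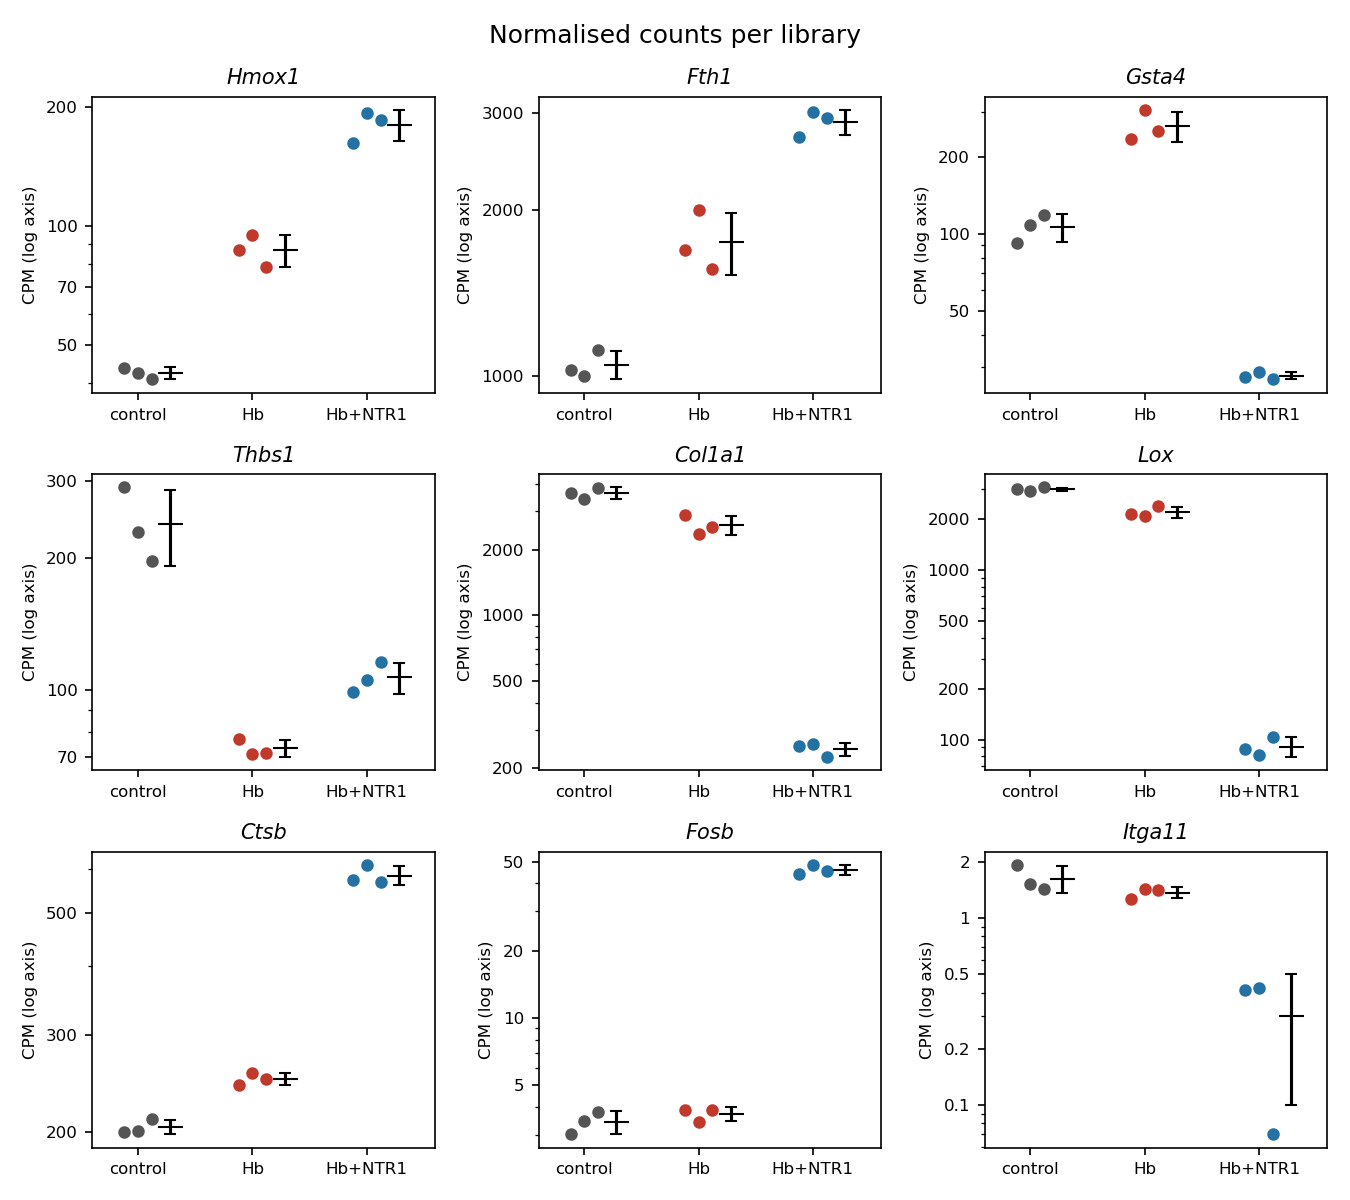
Normalised CPM on a log axis (y) in the 3 libraries of each group (x) for 9 genes, with the group mean and SD as the black bar beside the points (n = 3). Hmox1 and Fth1 were highest in Hb+NTR1, with means of 181 and 2884 CPM, whereas Gsta4 was highest in Hb, at 264 CPM.

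Hb+NTR1 was compared with Hb to ask what the added agent changed in oxyhemoglobin-treated cells. Col3a1, the chain of type III collagen, went from 1771 ± 40.1 CPM in Hb to 71.1 ± 3.07 CPM in Hb+NTR1, and Lox, which crosslinks collagen, from 2199 ± 156 to 91.0 ± 11.9 CPM. The transcription factor gene Fosb rose from 3.72 ± 0.263 to 46.0 ± 2.22 CPM and the lysosomal protease gene Ctsb from 249.6 ± 6.49 to 585 ± 23.03 CPM. Hmox1 rose again, from 86.8 ± 7.93 to 181 ± 16.1 CPM. A majority of tested genes differed, 8607 or 62.3%, with 4237 higher and 4370 lower in Hb+NTR1 by edgeR, and 2206 changed at least 2-fold, 855 higher and 1351 lower. Directions here and in the other comparisons are relative to the TMM scaling, after which the median log2 fold change of all tested genes was -0.0108 here. A shift shared by all genes would not show, so the near-equal split is not a measure of total RNA.

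The largest rises by the fixed rule were in Reps2, Tmem229b, Selp, Gbp4, Oit3, Nyx, Cpeb1, Lcp1, Fosb and Pgam2, and in each the 3 Hb+NTR1 libraries lay above the 3 Hb libraries. Reps2, Tmem229b and Selp lay under the floor in Hb. Reps2 had 0.0456 ± 0.0789 CPM in Hb and 5.88 ± 1.19 CPM in Hb+NTR1, Tmem229b 0.0456 ± 0.0789 and 5.37 ± 0.714 CPM, and the adhesion molecule Selp 0.0706 ± 0.122 and 6.03 ± 2.09 CPM. Lcp1, an actin-bundling protein, went from 0.859 ± 0.385 to 12.4 ± 0.790 CPM and Gbp4, an interferon-induced GTPase, from 0.313 ± 0.193 to 10.9 ± 1.11 CPM. Fosb rose 12.4-fold (log2 fold change 3.63 ± 0.124, edgeR adjusted p = 2.49e-17). The largest falls were in Prl2c2, Unc5c, Cdh26, Il1rl1, Ly6a, Plac1, Col3a1, Cp, Lox and Medag, again with no overlap of libraries. Unc5c, a netrin receptor, went from 16.5 ± 2.61 to 0.280 ± 0.212 CPM and the interleukin 33 receptor Il1rl1 from 22.7 ± 1.32 to 0.627 ± 0.285 CPM. Cp, the copper-carrying ferroxidase ceruloplasmin, went from 112 ± 21.1 to 4.54 ± 0.374 CPM. Col3a1 fell 24.9-fold (log2 fold change -4.64 ± 0.0742, edgeR adjusted p = 2.17e-23) and Lox 24.2-fold (log2 fold change -4.59 ± 0.0894, edgeR adjusted p = 1.00e-21). Ly6a and Prl2c2 have close relatives and are uncertain.

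Of the 25 lists, 8 passed in Hb+NTR1 against Hb, 3 up and 5 down. Among the 10 splits of these 6 libraries, 4 gave as many lists, the real one included, and the highest other gave 11. The number of lists that passed therefore does not set the real grouping apart. Extracellular matrix genes fell, with 5 higher, 26 lower and 1 not past the threshold of 32 members, and 5 higher and 26 lower adjusted over the list alone. For extracellular matrix genes the median log2 fold change was -1.33, with adjusted p = 5.26e-11, and adjusted p = 0.167 with an estimated correlation. Timp3, an inhibitor of matrix proteases, went from 162 ± 16.2 to 11.9 ± 0.750 CPM and the proteoglycan gene Dcn from 10.9 ± 1.91 to 0.995 ± 0.242 CPM. Fibroblast markers fell, with 0 higher, 9 lower and 0 not past the threshold of 9 members, and 0 higher and 9 lower adjusted over the list alone. For fibroblast markers the median log2 fold change was -2.97, with adjusted p = 1.57e-07, and adjusted p = 0.146 with an estimated correlation. Pdgfrb, a growth factor receptor, went from 85.2 ± 13.8 to 6.23 ± 0.143 CPM and Col1a1 from 2598 ± 262 to 245 ± 16.96 CPM. Integrated stress response genes fell, with 3 higher, 22 lower and 2 not past the threshold of 27 members, and 3 higher and 22 lower adjusted over the list alone. For integrated stress response genes the median log2 fold change was -0.83, with adjusted p = 1.16e-08, and adjusted p = 0.167 with an estimated correlation. Pck2, a mitochondrial enzyme of gluconeogenesis, went from 196 ± 10.5 to 42.9 ± 1.93 CPM, Shmt2, a mitochondrial enzyme of serine metabolism, from 479.5 ± 40.4 to 114 ± 8.84 CPM and the glycine transporter Slc6a9 from 103 ± 7.86 to 27.1 ± 3.19 CPM. Fgf21, a secreted growth factor, had 1.28 ± 0.265 CPM in Hb and 0.0932 ± 0.0808 CPM in Hb+NTR1. Ddit3, a member of this list that encodes a stress-induced transcription factor, went the other way, from 34.2 ± 4.32 to 49.6 ± 2.86 CPM (edgeR adjusted p = 3.21e-05).

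YAP and SRF target genes fell, with 3 higher, 11 lower and 1 not past the threshold of 15 members, and 3 higher and 11 lower adjusted over the list alone. For YAP and SRF target genes the median log2 fold change was -0.64, with adjusted p = 0.0182, and adjusted p = 0.416 with an estimated correlation. The receptor tyrosine kinase Axl went from 468 ± 49.7 to 197 ± 13.4 CPM and the tropomyosin gene Tpm1 from 367 ± 22.9 to 155 ± 8.995 CPM. Actg2, an actin with 0.798 ± 0.319 CPM in Hb and 0.324 ± 0.160 CPM in Hb+NTR1, was called at edgeR adjusted p = 0.0414 and missed by DESeq2 (adjusted p = 0.121), with no filter on low counts (adjusted p = 0.0785), without Hb replicate 2 or 3 (adjusted p = 0.223 and 0.0511) and without Hb+NTR1 replicate 1, 2 or 3 (adjusted p = 0.0595, 0.0573 and 0.184). Astrocyte markers fell, with 0 higher, 5 lower and 0 not past the threshold of 5 members, and 0 higher and 5 lower adjusted over the list alone. For astrocyte markers the median log2 fold change was -0.50, with adjusted p = 0.0182, and adjusted p = 0.167 with an estimated correlation. The glutamate transporter gene Slc1a3 went from 123 ± 12.3 to 7.07 ± 0.477 CPM. The transcription factor gene Sox9 went from 87.5 ± 0.564 to 61.7 ± 8.50 CPM, the connexin gene Gja1 from 118 ± 4.64 to 84.1 ± 3.28 CPM and Aldh1l1 from 0.833 ± 0.330 to 0.138 ± 0.137 CPM. The call of the astrocyte list ended with any 1 of the 3 Hb libraries or with Hb+NTR1 replicate 1 left out, with an adjusted p of 0.0492 to 0.102 over all libraries left out in turn.

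Immediate early genes rose, with 19 higher, 5 lower and 1 not past the threshold of 25 members, and 20 higher and 5 lower adjusted over the list alone. For immediate early genes the median log2 fold change was 0.82, with adjusted p = 1.77e-05, and adjusted p = 0.167 with an estimated correlation. Fos went from 8.05 ± 1.13 to 64.0 ± 9.08 CPM, the antiproliferative Btg2 from 15.3 ± 0.319 to 91.7 ± 5.59 CPM and the nuclear receptor gene Nr4a3 from 0.450 ± 0.0424 to 2.06 ± 0.269 CPM. Autophagy and lysosome genes rose, with 21 higher, 2 lower and 3 not past the threshold of 26 members, and 21 higher and 2 lower adjusted over the list alone. For autophagy and lysosome genes the median log2 fold change was 0.75, with adjusted p = 1.79e-08, and adjusted p = 0.146 with an estimated correlation. Hexa went from 87.7 ± 5.31 to 205 ± 5.26 CPM and the lysosomal cholesterol exporter Npc1 from 42.4 ± 5.11 to 109 ± 1.71 CPM. Mitochondrially encoded genes, whose share of the counts was highest in Hb+NTR1, rose, with 10 higher, 0 lower and 3 not past the threshold of 13 members, and 10 higher and 0 lower adjusted over the list alone. For mitochondrially encoded genes the median log2 fold change was 0.49, with adjusted p = 9.94e-04, and adjusted p = 0.298 with an estimated correlation. They included mt-Nd5, from 3087 ± 207 to 5549 ± 262 CPM, mt-Cytb, from 7203 ± 442 to 11805 ± 137 CPM, and mt-Nd6, from 479 ± 81.0 to 724 ± 26.7 CPM. Reads of mt-Co3, at 18.2 ± 0.930 and 28.9 ± 1.39 CPM, can be shared with nuclear copies, so its rise is uncertain.

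Genes fixed for apoptosis moved in different directions. Bax fell from 41.7 ± 7.21 to 20.4 ± 2.25 CPM (log2 fold change -1.03 ± 0.118, edgeR adjusted p = 6.17e-08) and the anti-apoptotic Bcl2 rose from 7.67 ± 2.097 to 17.7 ± 2.21 CPM (log2 fold change 1.21 ± 0.157, edgeR adjusted p = 4.44e-07). Cdkn1a rose from 108 ± 6.17 to 182 ± 16.5 CPM and Slc7a11, the cystine transporter, fell from 37.0 ± 5.36 to 23.2 ± 1.80 CPM. The other 17 lists did not pass in Hb+NTR1 against Hb. Pro-apoptotic genes had 9 higher and 6 lower of 23 (9 and 6 adjusted over the list alone), at a median log2 of 0.21 and adjusted p = 0.463. Anti-apoptotic genes had 7 higher and 1 lower of 15 (7 and 1 adjusted over the list alone), at a median log2 of 0.20 and adjusted p = 0.0948. Ferroptosis regulators had 11 higher and 5 lower of 20 (11 and 5 adjusted over the list alone), at a median log2 of 0.39 and adjusted p = 0.0721. Heme and iron handling had 15 higher and 5 lower of 27 (15 and 5 adjusted over the list alone), at a median log2 of 0.34 and adjusted p = 0.0695. NRF2 target genes had 13 higher and 8 lower of 23 (13 and 8 adjusted over the list alone), at a median log2 of 0.41 and adjusted p = 0.0858. Cholesterol synthesis genes had 6 higher and 14 lower of 25 (7 and 14 adjusted over the list alone), at a median log2 of -0.29 and adjusted p = 0.0858. Neuronal markers had 1 higher and 5 lower of 8 (1 and 5 adjusted over the list alone), at a median log2 of -0.50 and adjusted p = 0.0874. Hypoxia and glycolysis genes had 7 higher and 16 lower of 32 (7 and 16 adjusted over the list alone), at a median log2 of -0.25 and adjusted p = 0.0935. Heat shock genes had 9 higher and 4 lower of 19 (9 and 4 adjusted over the list alone), at a median log2 of 0.050 and adjusted p = 0.147. The p53 target genes had 10 higher and 7 lower of 23 (10 and 8 adjusted over the list alone), at a median log2 of 0.15 and adjusted p = 0.164. Oxidative phosphorylation genes had 8 higher and 9 lower of 34 (8 and 9 adjusted over the list alone), at a median log2 of 0.0092 and adjusted p = 0.948. Endoplasmic reticulum chaperones had 8 higher and 8 lower of 22 (8 and 8 adjusted over the list alone), at a median log2 of -0.00072 and adjusted p = 0.833. DNA replication genes had 8 higher and 15 lower of 30 (8 and 15 adjusted over the list alone), at a median log2 of -0.16 and adjusted p = 0.245. Mitotic genes had 6 higher and 10 lower of 30 (6 and 10 adjusted over the list alone), at a median log2 of -0.027 and adjusted p = 0.463. Interferon-stimulated genes had 10 higher and 3 lower of 23 (10 and 3 adjusted over the list alone), at a median log2 of 0.38 and adjusted p = 0.287. NF-kB and inflammatory genes had 8 higher and 9 lower of 18 (8 and 10 adjusted over the list alone), at a median log2 of -0.31 and adjusted p = 0.592. Integrin subunits had 7 higher and 5 lower of 17 (7 and 5 adjusted over the list alone), at a median log2 of -0.013 and adjusted p = 0.513. The mean lay at -0.012 for the pro-apoptotic list, whose median and camera direction were positive, and at -0.0054 for the oxidative phosphorylation list, likewise positive by median and camera. Without Hb replicate 2, camera at the preset correlation called 3 of these lists, all up, namely ferroptosis regulators, NRF2 target genes and heat shock genes (adjusted p = 0.0332, 0.0332 and 0.0399). For the integrin list the median and the mean of -0.24 were negative and the camera direction was up.

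The libraries of both groups did not overlap for 8937 genes, or 64.7%, where chance gives 10%. The count of called genes became 7909 to 8613 with 1 library of either group left out. The split turned to 4455 higher and 4184 lower under library totals alone and to 4164 and 4015 by DESeq2, or 51.6% and 50.9% higher against 49.2%.

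**Figure D2:**
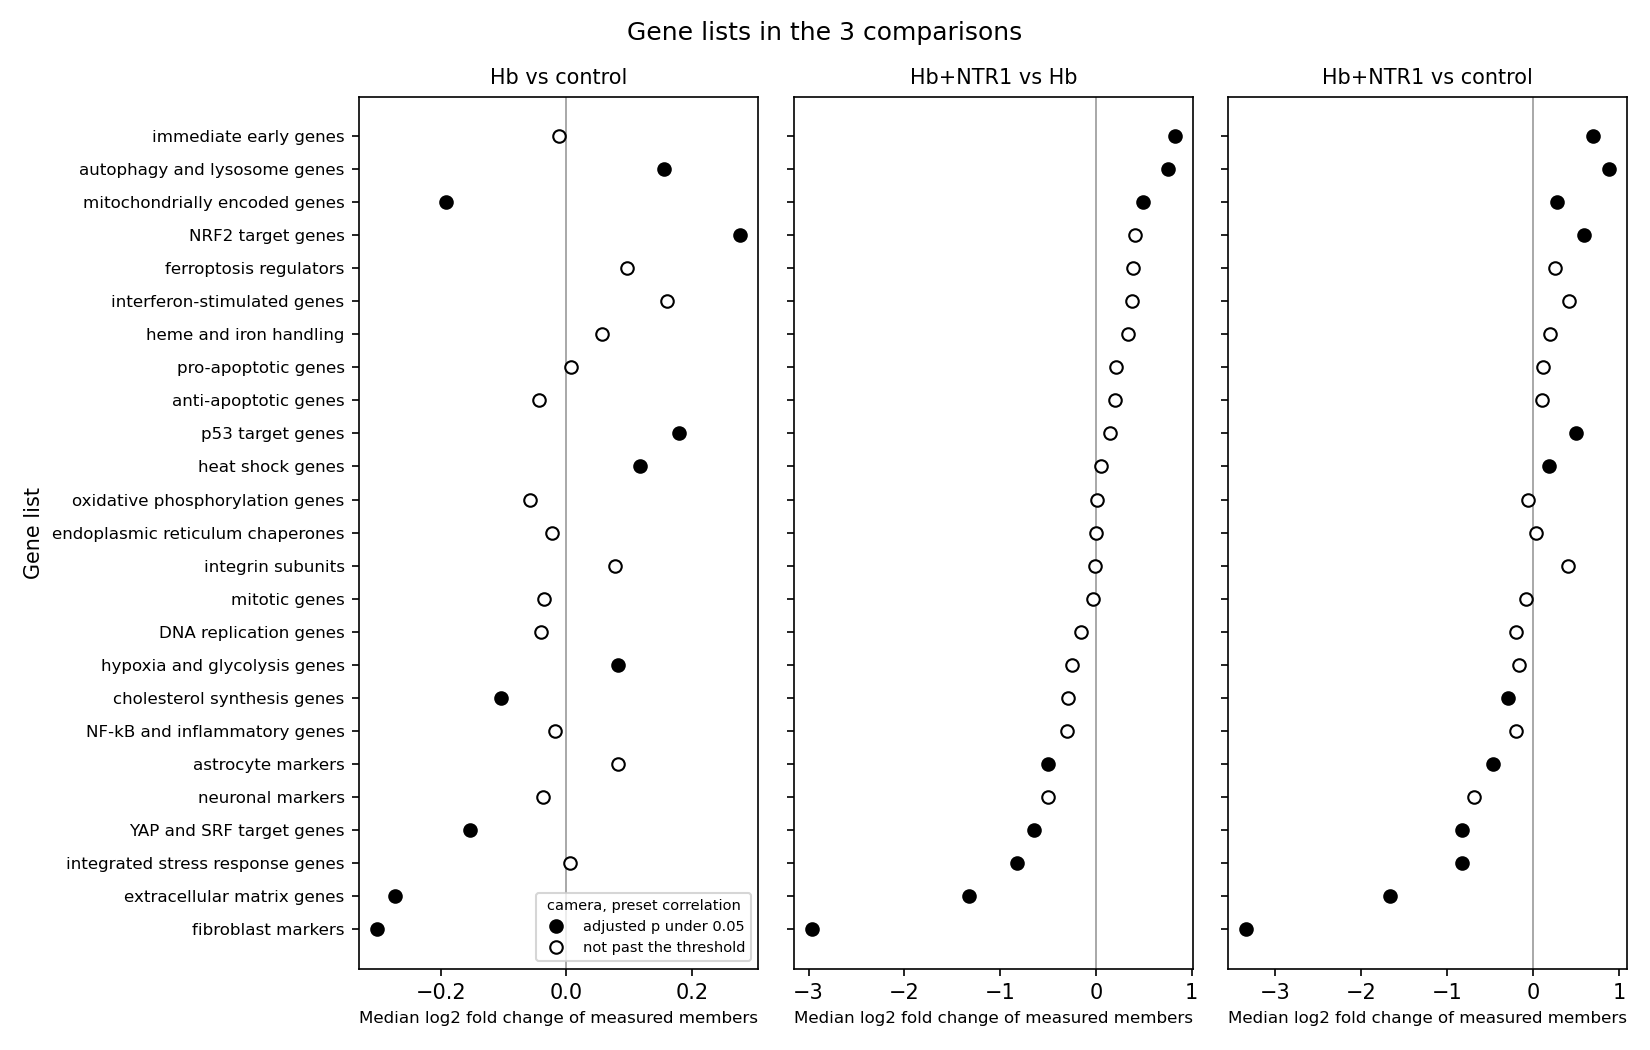
Median log2 fold change of the measured members (x) of the 25 tested gene lists (y) in the 3 comparisons, with filled points for an adjusted p under 0.05 by camera at the preset correlation. The x axes differ in range. Fibroblast markers lay lowest in every comparison, at -0.30, -2.97 and -3.34.

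Itga11, the integrin alpha 11 subunit that binds collagen and the gene named in the title of the series (ENSMUSG00000032243.8, chromosome 9, 62677826 to 62783982, plus strand, GRCm38), was expressed at a low level. It had 1.63 ± 0.262 CPM in control, 1.37 ± 0.0882 CPM in Hb and 0.301 ± 0.2002 CPM in Hb+NTR1 (SD, n = 3). The counts behind these levels were 32, 23 and 20 in control, 18, 21 and 19 in Hb and 6, 6 and 1 in Hb+NTR1. Between Hb and control the log2 fold change was -0.25 ± 0.357 (edgeR adjusted p = 0.788), so no difference was detectable at this depth. Itga11 fell in Hb+NTR1 against Hb (log2 fold change -2.16 ± 0.475, edgeR adjusted p = 3.89e-04) and against control (log2 fold change -2.41 ± 0.460, edgeR adjusted p = 7.78e-05), in 3 of 3 libraries each. Rtn4r and Ntsr1, whose protein products share the names NgR1 and NTR1, had 0 counts in every library.

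Hb+NTR1 was compared with control to ask how far the doubly treated cells stood from untreated cells. They had 71.1 ± 3.07 CPM of Col3a1 against 1547 ± 82.9 in control, and 91.0 ± 11.9 CPM of Lox against 3007 ± 64.6. Hmox1 stood at 181 ± 16.1 CPM against 42.4 ± 1.47 in control, a 4.26-fold rise (log2 fold change 2.09 ± 0.0802, edgeR adjusted p = 1.89e-16), and Fth1 at 2884 ± 150.02 CPM against 1049 ± 61.4. Fosb went from 3.42 ± 0.394 to 46.0 ± 2.22 CPM. By edgeR 8782 genes differed, 63.6% of those tested, 4340 higher and 4442 lower, with 951 and 1380 of these changed at least 2-fold.

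The largest rises were in Reps2, Tmem229b, Cpeb1, Gbp4, Selp, Nyx, Oit3, Lcp1, Pgam2 and Fosb, with all 3 Hb+NTR1 libraries above the 3 control libraries. Reps2 had 0 counts in all 3 control libraries, where the floor was 0.178 to 0.209 CPM, and 5.88 ± 1.19 CPM in Hb+NTR1. The muscle phosphoglycerate mutase gene Pgam2 went from 0.606 ± 0.225 to 8.45 ± 0.406 CPM. The largest falls were in Unc5c, Cdh26, Prelp, Rcan2, Lox, Slc1a3, Calml4, Cp, Il1rl1 and S1pr3. Lox fell 33.0-fold (log2 fold change -5.05 ± 0.0911, edgeR adjusted p = 1.78e-22) and Slc1a3 29.8-fold (log2 fold change -4.90 ± 0.0984, edgeR adjusted p = 1.40e-21), and S1pr3, a sphingosine 1-phosphate receptor, went from 19.99 ± 2.63 to 0.834 ± 0.0104 CPM.

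Of the lists, 12 passed against control, 6 up and 6 down. Extracellular matrix genes fell, with 3 higher, 26 lower and 3 not past the threshold of 32 members, and 3 higher and 26 lower adjusted over the list alone. For extracellular matrix genes the median log2 fold change was -1.67, with adjusted p = 3.62e-14, and adjusted p = 0.195 with an estimated correlation. Timp3 stood at 236 ± 6.36 and 11.9 ± 0.750 CPM in control and Hb+NTR1. Fibroblast markers fell, with 0 higher, 9 lower and 0 not past the threshold of 9 members, and 0 higher and 9 lower adjusted over the list alone. For fibroblast markers the median log2 fold change was -3.34, with adjusted p = 1.27e-08, and adjusted p = 0.0926 with an estimated correlation. Pdgfrb stood at 104 ± 6.98 and 6.23 ± 0.143 CPM and Col1a1 at 3624 ± 221 and 245 ± 16.96 CPM. Integrated stress response genes fell, with 2 higher, 21 lower and 4 not past the threshold of 27 members, and 2 higher and 23 lower adjusted over the list alone. For integrated stress response genes the median log2 fold change was -0.83, with adjusted p = 1.27e-08, and adjusted p = 0.195 with an estimated correlation. Pck2 stood at 207 ± 9.17 and 42.9 ± 1.93 CPM and Shmt2 at 490.0 ± 10.6 and 114 ± 8.84 CPM. YAP and SRF target genes fell, with 3 higher, 12 lower and 0 not past the threshold of 15 members, and 3 higher and 12 lower adjusted over the list alone. For YAP and SRF target genes the median log2 fold change was -0.83, with adjusted p = 0.00329, and adjusted p = 0.302 with an estimated correlation. Acta2 stood at 20.5 ± 5.46 and 5.35 ± 0.151 CPM and Amotl2 at 296 ± 23.03 and 126 ± 8.41 CPM. Actg2 was called (edgeR adjusted p = 0.0169) but missed by DESeq2 (adjusted p = 0.0649) and without control replicate 1 (adjusted p = 0.0904) or Hb+NTR1 replicate 3 (adjusted p = 0.0993). Cholesterol synthesis genes fell, with 3 higher, 14 lower and 8 not past the threshold of 25 members, and 4 higher and 14 lower adjusted over the list alone. For cholesterol synthesis genes the median log2 fold change was -0.29, with adjusted p = 0.0111, and adjusted p = 0.302 with an estimated correlation. Pmvk, of the mevalonate pathway, stood at 50.1 ± 0.548 and 17.2 ± 2.79 CPM and Mvd at 63.3 ± 4.89 and 31.1 ± 4.04 CPM. Astrocyte markers fell, with 0 higher, 4 lower and 1 not past the threshold of 5 members, and 0 higher and 4 lower adjusted over the list alone. For astrocyte markers the median log2 fold change was -0.47, with adjusted p = 0.0225, and adjusted p = 0.195 with an estimated correlation. The list missed without control replicate 1, 2 or 3 and without Hb+NTR1 replicate 1 (adjusted p from 0.0459 to 0.127 over all libraries left out). Aldh1l1, of this list, went from 0.723 ± 0.514 to 0.138 ± 0.137 CPM (edgeR adjusted p = 0.0122) and missed without control replicate 1 or 3 or Hb+NTR1 replicate 3 (adjusted p = 0.0558, 0.0604 and 0.0682).

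Autophagy and lysosome genes rose, with 22 higher, 1 lower and 3 not past the threshold of 26 members, and 22 higher and 1 lower adjusted over the list alone. For autophagy and lysosome genes the median log2 fold change was 0.88, with adjusted p = 1.55e-09, and adjusted p = 0.107 with an estimated correlation. Ctsb stood at 204 ± 6.29 and 585 ± 23.03 CPM and Gpnmb at 174 ± 5.63 and 474 ± 9.30 CPM. The immediate early genes rose, with 19 higher, 5 lower and 1 not past the threshold of 25 members, and 19 higher and 5 lower adjusted over the list alone. For immediate early genes the median log2 fold change was 0.70, with adjusted p = 8.54e-05, and adjusted p = 0.195 with an estimated correlation. NRF2 target genes rose, with 13 higher, 5 lower and 5 not past the threshold of 23 members, and 13 higher and 5 lower adjusted over the list alone. For NRF2 target genes the median log2 fold change was 0.59, with adjusted p = 0.00193, and adjusted p = 0.302 with an estimated correlation. The thioredoxin reductase gene Txnrd1 went from 259.8 ± 1.92 to 817 ± 44.0 CPM and the sulfiredoxin gene Srxn1 from 97.0 ± 2.98 to 335 ± 17.2 CPM, but Gsta4 fell from 106 ± 13.04 to 27.7 ± 0.870 CPM. The p53 target genes rose, with 13 higher, 5 lower and 5 not past the threshold of 23 members, and 13 higher and 5 lower adjusted over the list alone. For p53 target genes the median log2 fold change was 0.49, with adjusted p = 0.0218, and adjusted p = 0.302 with an estimated correlation. Cdkn1a and the stress protein gene Trp53inp1 rose, from 29.8 ± 2.47 to 108 ± 11.02 CPM for the latter, while the pro-apoptotic Bbc3 fell from 19.9 ± 1.77 to 9.82 ± 1.27 CPM and Bax from 29.2 ± 2.82 to 20.4 ± 2.25 CPM. Heat shock genes rose, with 10 higher, 4 lower and 5 not past the threshold of 19 members, and 10 higher and 4 lower adjusted over the list alone. For heat shock genes the median log2 fold change was 0.18, with adjusted p = 0.0225, and adjusted p = 0.479 with an estimated correlation. Dnajb4, a co-chaperone, stood at 56.3 ± 4.31 and 109 ± 6.34 CPM and Cryab, a small heat shock protein that fell, at 63.4 ± 1.76 and 34.1 ± 2.05 CPM. Mitochondrially encoded genes rose, with 9 higher, 0 lower and 4 not past the threshold of 13 members, and 9 higher and 0 lower adjusted over the list alone. For mitochondrially encoded genes the median log2 fold change was 0.28, with adjusted p = 0.0225, and adjusted p = 0.421 with an estimated correlation.

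The other 13 lists did not pass in Hb+NTR1 against control. Heme and iron handling had 14 higher and 6 lower of 27 (14 and 6 adjusted over the list alone), at a median log2 of 0.19 and adjusted p = 0.0590. Neuronal markers had 1 higher and 5 lower of 8 (1 and 5 adjusted over the list alone), at a median log2 of -0.69 and adjusted p = 0.0703. Ferroptosis regulators had 11 higher and 5 lower of 20 (11 and 5 adjusted over the list alone), at a median log2 of 0.25 and adjusted p = 0.0703. Interferon-stimulated genes had 11 higher and 3 lower of 23 (11 and 3 adjusted over the list alone), at a median log2 of 0.42 and adjusted p = 0.123. DNA replication genes had 8 higher and 16 lower of 30 (8 and 16 adjusted over the list alone), at a median log2 of -0.20 and adjusted p = 0.144. Mitotic genes had 6 higher and 12 lower of 30 (6 and 12 adjusted over the list alone), at a median log2 of -0.081 and adjusted p = 0.230. Anti-apoptotic genes had 5 higher and 1 lower of 15 (4 and 1 adjusted over the list alone), at a median log2 of 0.11 and adjusted p = 0.232. Pro-apoptotic genes had 11 higher and 8 lower of 23 (11 and 8 adjusted over the list alone), at a median log2 of 0.11 and adjusted p = 0.462. Hypoxia and glycolysis genes had 8 higher and 12 lower of 32 (8 and 12 adjusted over the list alone), at a median log2 of -0.17 and adjusted p = 0.318. Integrin subunits had 8 higher and 6 lower of 17 (8 and 6 adjusted over the list alone), at a median log2 of 0.41 and adjusted p = 0.326. NF-kB and inflammatory genes had 6 higher and 9 lower of 18 (6 and 9 adjusted over the list alone), at a median log2 of -0.20 and adjusted p = 0.484. Oxidative phosphorylation genes had 6 higher and 10 lower of 34 (6 and 10 adjusted over the list alone), at a median log2 of -0.065 and adjusted p = 0.497. Endoplasmic reticulum chaperones had 8 higher and 7 lower of 22 (8 and 7 adjusted over the list alone), at a median log2 of 0.034 and adjusted p = 0.974. The mean went against a positive median and camera direction for the integrin list (-0.012) and the pro-apoptotic list (-0.0062), and the chaperone list had a positive median, a mean of -0.044 and a direction of down. The lists of ferroptosis regulators and of heme and iron handling passed camera at the preset correlation, up, once Hb+NTR1 replicate 1 was left out (adjusted p = 0.0463 for both). The count of called genes became 8006 to 8218 with 1 library of either group left out, and the libraries did not overlap for 9649 genes, or 69.9%, where chance gives 10%. Here the split turned to 4823 higher and 3933 lower under library totals alone and to 4245 and 4084 by DESeq2, or 55.1% and 51.0% higher against 49.4%. It was 4007 and 3999 without Hb+NTR1 replicate 1.

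The remaining 4 lists had fewer than 5 measured members and were not tested as groups. All 4 measured metallothionein and zinc response genes rose in Hb+NTR1 against Hb, with a median log2 fold change of 1.98. Of the microglia and macrophage markers, 3 were measured, and 2 of them rose and 1 fell in Hb+NTR1 against Hb. The 1 measured oligodendrocyte marker fell in Hb+NTR1 against Hb, by a log2 fold change of -0.64, and the 1 measured erythroid marker did not pass in any comparison. Against control, all 4 zinc response genes were higher in Hb+NTR1 (median 1.64), 2 microglia markers were higher and 1 lower, and the oligodendrocyte marker was lower (-1.45). In Hb against control 1 microglia marker was higher and 1 lower, and no member of the other 3 lists passed by edgeR.

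Genes changed by oxyhemoglobin were followed into Hb+NTR1 to ask whether the added agent moved them back. Of the 504 genes called in Hb against control, 203 changed in the opposite direction in Hb+NTR1 against Hb, 210 changed further in the same direction and 91 were not called. Gsta4 rose to 264 ± 36.4 CPM in Hb and fell to 27.7 ± 0.870 CPM in Hb+NTR1, below its control level, as did Itgb7, at 26.0 ± 3.87 and 4.93 ± 1.09 CPM. Fstl1 fell to 43.8 ± 2.53 CPM in Hb and stood at 89.7 ± 5.73 CPM in Hb+NTR1, where control had 92.3 ± 5.84 CPM (edgeR adjusted p = 0.637 for Hb+NTR1 against control). The transcription factor genes Egr3 and Etv5 fell in Hb and rose past control in Hb+NTR1, with Etv5 at 14.7 ± 0.558, 7.87 ± 0.771 and 36.5 ± 3.96 CPM. Others with the largest opposite changes were Prl2c2, Ifi202b, Aldh3a1, Shc2 and Dmpk. Hmox1, Fth1 and Cdkn1a were among the genes that rose in both steps.

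Independent lists would give 157 opposite and 157 same-direction genes. Of the genes up in Hb, 120 then fell and 90 rose, against 82.0 and 79.5 from independent lists, and of those down in Hb 83 then rose and 120 fell, against 75.2 and 77.5. The Hb libraries enter both comparisons, and 20 simulations with no group effect gave no gene called in both. These simulations called at most 1 gene in Hb against control, so the absence of genes called in both is no measure for the counts seen. Across genes, which are not independent replicates, the log2 fold changes had a correlation of -0.07 against -0.51 in the simulations, and a covariance of -0.0222 against -0.0227, a difference of 5.57e-04. Simulated correlations, here and against control below, are not comparable with the real ones, which also hold the spread of group effects. The real covariance lay within the simulated range of -0.0248 to -0.0210, so shared libraries alone could give it. With the Hb libraries split so that none entered both comparisons, 1 in one and 2 in the other, 6 fits gave 49 to 333 opposite and 54 to 539 same-direction genes. Same-direction genes outnumbered opposite ones in 5 of the 6. The covariance then ran from -0.0127 to 0.0242 and the correlation from -0.0287 to 0.0647. The opposite count lay above that of independent lists in 5 of the 6 fits and the same-direction count in all 6, so the excess was not particular to opposite changes. The opposite count was 444 without Hb replicate 2, 117 without control replicate 2 and 111 without control replicate 3. Against control, 300 of the 504 genes were called in the same direction in Hb+NTR1, 119 in the opposite direction and 85 not at all, where independent lists would give 160 and 160. Here the control libraries are shared, the correlation was 0.27 against 0.49 simulated, and the covariance was 0.0828 against 0.0221, a difference of 0.0607. With the control libraries split in the same way, the covariance was 0.0523 to 0.0820 and same-direction genes outnumbered opposite ones in 6 of 6 fits.

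**Figure D3:**
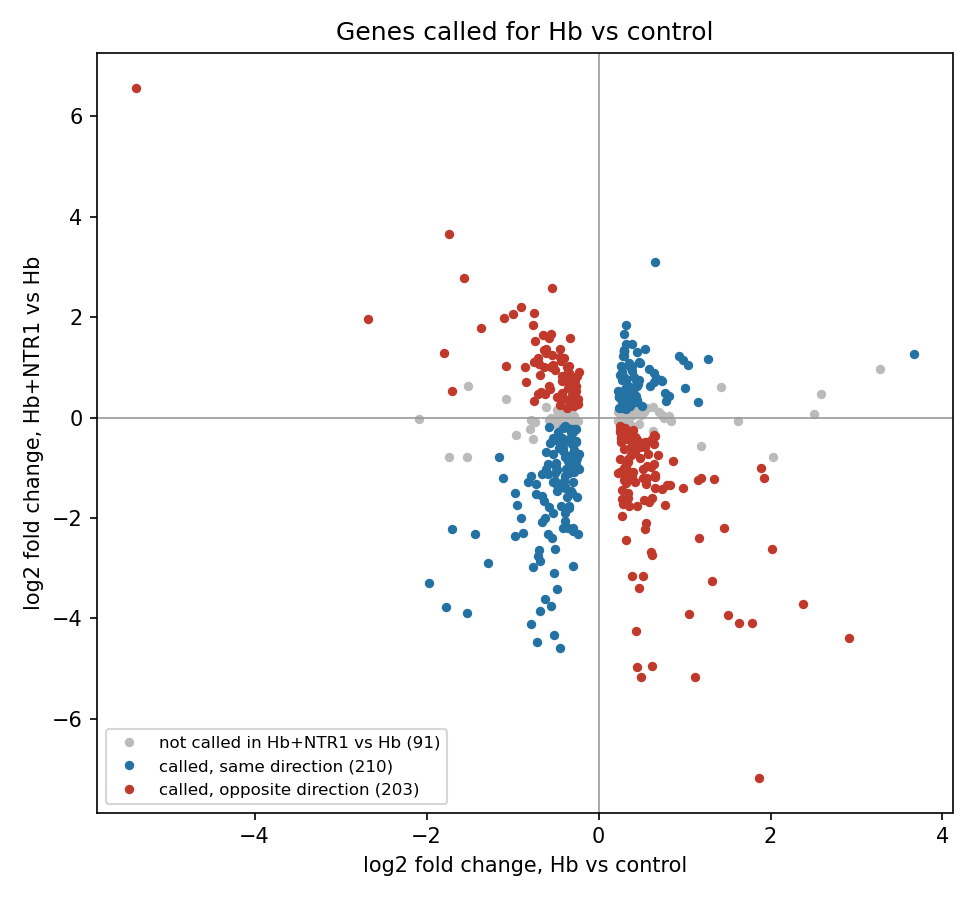
Log2 fold change of Hb+NTR1 against Hb (y) and of Hb against control (x) for the 504 genes called in Hb against control, each point a gene. The 203 genes called in the opposite direction (red) and the 210 called in the same direction (blue) were nearly equal in number.

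The authors' deposited table for Hb+NTR1 against control lists 691 genes, 327 up and 364 down, all with an absolute log2 fold change of at least 2.005 and an adjusted p of at most 0.00994. Of these, 562 were tested here, and all 562 were called by edgeR in the same direction as in the authors' deposited table, while the other 129 had too few counts. Across the shared genes, which are not independent replicates, the correlation of the log2 fold changes here with those of the authors' deposited table was 0.999. Both rest on the same counts and that table holds only large changes, so these values could hardly have come out otherwise. They check the processing alone. Itga11 stands in the authors' deposited table at a log2 fold change of -2.44 and an adjusted p = 5.35e-04. With the same limits, 610 genes were called here, of which 559 are in the authors' deposited table.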

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

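Library totals alone, removal of mitochondrially encoded genes and the split of shared libraries were chosen after the data had been seen. Under DESeq2 size factors, no filter, the strict filter, DESeq2, the 6 libraries compared, library totals alone and removal of mitochondrially encoded genes, Hb against control gave 510, 616, 499, 512, 371, 573 and 501 genes against 504. Hb+NTR1 against Hb gave 8625, 8767, 8419, 8179, 8253, 8639 and 8607 genes against 8607, and Hb+NTR1 against control 8789, 8981, 8540, 8329, 9255, 8756 and 8780 against 8782. With 1 library left out in turn, the ranges were 285 (without control replicate 2) to 1125 (without Hb replicate 2), 7909 to 8613 and 8006 to 8218. Without control replicates 1 and 3 the Hb against control count was 315 and 286. The cause of these moves was not tested. With an absolute log2 fold change of at least 1 required, 51, 2206 and 2331 genes passed, since most called changes were smaller.

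The count of opposite changes, 203, was 206, 250, 202 and 193 under DESeq2 size factors, no filter, the strict filter and DESeq2. It ranged from 111 (without control replicate 3) to 444 (without Hb replicate 2), with 117 without control replicate 2, and was 24 with an absolute log2 fold change of at least 1. With the Hb libraries split between the 2 comparisons it was 176, 333 and 49 with Hb replicate 1, 2 or 3 alone in Hb against control, and 124, 299 and 167 with that library alone in Hb+NTR1 against Hb. The same-direction counts of these 6 fits were 150, 403, 54, 176, 539 and 187, against 210.

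Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons, against 10, 8 and 12 with the preset one, with lowest adjusted p-values of 0.0941, 0.146 and 0.0926. Fry called 10, 24 and 23. Fry asks whether the genes of a list move one way and does not set them against other genes, and with most genes changed in the Hb+NTR1 comparisons many lists pass it. With 1 library left out 10 to 12, 7 to 10 and 11 to 13 lists passed.

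Itga11 had a log2 fold change of -0.34 to -0.11, -2.46 to -1.70 and -2.72 to -1.95 with 1 library left out, with adjusted p-values of 0.747 to 0.938, 8.30e-04 to 0.00499 and 1.94e-04 to 0.00131. Its calls were the same in all alternatives run.

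For the named genes 2199 values over 184 pairs of gene and comparison were computed. Of these 2149 gave the same direction and call, 45 no longer passed and 5 changed sign. The 5 were all in genes without a call in that comparison. In Hb against control Bcl2 ran from -0.282 without Hb replicate 1 to 0.112 without Hb replicate 2. In Hb+NTR1 against control Fstl1 ran from -0.0780 without control replicate 3 to 0.0136 without Hb+NTR1 replicate 1. The cause was not tested.

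Replicates of different groups share only a number. As a block, that number gave 645 genes (316 higher and 329 lower), 8706 and 8898, an opposite count of 263, and 10, 8 and 12 lists, and 184 of 184 named values were the same. The 9 pairs of libraries with the same number had residual correlations across genes of -0.0526 to 0.262, 3 of them over 0.1, and 5 of 9 libraries were closest to a library of their own number.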

Other observations

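The tests of total counts, of the share of abundant genes, of chromosome content, of macrophage genes and of synthetase genes per library, and the lists of ribosomal protein, V-ATPase, lysosomal enzyme and synthetase genes, were chosen after results had been seen. Genes named in this part outside the fixed rule were picked from their values.

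The first pattern was the 8607 genes changed between Hb+NTR1 and Hb. The mean total counts of both groups differed by 0.461%, less than the SD between Hb libraries, which argues against unequal depth. Thinning every library to the smallest total, the test fixed beforehand, left 8463 called genes but removed only 4.84% of the counts, too little to test depth. The 100 most abundant genes took 19.1% of the counts in Hb and 17.8% in Hb+NTR1. With no trimming this would shift all other genes by a log2 of 0.0226, and by at most 0.0333 between any 2 libraries, against 0.136 for the smallest called change, which argues against a few genes shifting the scale. Leaving these genes out, the test fixed beforehand, left 8524 called genes but moved the other log2 fold changes by a median of only 0.00288, too little to test it. The largest median log2 fold change of any of 20 chromosomes was 0.141 in size, on chromosome 7, which argues against a mix-up with a line of other chromosome content. An effect of the added agent may explain the change, but with no group given the agent alone it could not be set apart from its combination with oxyhemoglobin. The labels do not say whether the groups were grown and processed together. A difference of culture or batch between the groups could therefore not be told apart from an effect of the agent.

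Cd68 and Lyz2, lysosomal genes abundant in macrophages, rose in Hb+NTR1, from 5.25 to 45.9 CPM and from 1.68 to 16.3 CPM by library totals. Another 6 macrophage genes together reached 1.91% of the CPM that Cd68 gained, which argues against macrophages among the cells. Of 30 lysosomal enzyme genes outside the fixed lists, 90% were higher, with a median log2 fold change of 0.76, and 15 of 16 V-ATPase genes, which acidify lysosomes, were higher as well (median 1.13). A rise of lysosomal genes as a group may therefore include Cd68 and Lyz2, but both rose far more than these medians. A shared rise of that size would account for only part of their change. The cause of the group rise was not tested.

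The integrated stress response list fell in Hb+NTR1. The median of its 26 members with a known length was -0.92, against a central range of -0.29 to 0.22 in 10000 random lists matched on exon length and expression, which argues against gene length bias. Synthetase genes known as targets of the transcription factor ATF4 had a median of -0.75 over 13 genes, all lower, against 0.12 over the other 7, of which 2 were higher, 3 lower and 2 not called (exact one-sided permutation p = 0.00108). That p counts genes, which are not independent replicates, as separate units. Per library, target genes minus other genes had a mean log2 of 1.19 ± 0.0268 in Hb and 0.524 ± 0.0186 in Hb+NTR1 (SD, n = 3), with no overlap. Lower ATF4-driven transcription may explain the fall, although 3 of the 27 measured list members, Ddit3 among them, rose. Ribosomal protein genes, in neither synthetase group, also fell by a median of -0.75. A fall of this size was therefore not particular to the ATF4 targets.

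Ribosomal protein genes were lower in Hb+NTR1 than in Hb in 84 of 86 cases, with a median log2 fold change of -0.75. This median ran from -0.75 to -0.72 under the 4 scalings, which lie too close together to test its sign. Pseudogenes make single ribosomal protein genes uncertain. In Hb against control 1 of them was lower. The zinc exporter gene Slc30a1 went from 12.99 CPM in Hb to 50.04 CPM in Hb+NTR1 with the metallothioneins, while the neuronal tubulin gene Tubb3 went from 36.8 to 5.26 CPM.

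The 3 libraries of each group allow 10 splits of any 6, too few for a share under 0.05. The real splits gave 504, 8607 and 8782 genes, where the highest other split gave 0, 0 and 0. The real split was the 1 of 10 as large in each. Every other split places libraries of both groups on each side, so a real difference adds to the spread within sides and hinders calls. Counts of 0 could hardly have come out otherwise there and do not measure chance. For lists the real splits gave 10, 8 and 12 and the highest others 8, 11 and 8, with 1, 4 and 1 of 10 splits as large. In Hb+NTR1 against Hb the number of lists called therefore does not set the real split apart. For the opposite count, 3 of 100 arrangements of the 9 libraries, the real one included, gave 203 or more. The highest other count was 7654, many times the real one. A count of that size needs as many calls in both comparisons. The Hb+NTR1 libraries give this when they take the place of the Hb group, which both comparisons share. Their distance from the other 6 then enters both comparisons with opposite signs, so such a count is not comparable with 203. Only these 3 arrangements kept the Hb+NTR1 libraries together, and the other 97 gave 0 or 1 gene. These arrangements therefore do not decide whether chance can be excluded for the 203.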
